A study of Mus musculus with 6 samples.

How the data were processed

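RNA was sequenced from YFP-positive cells sorted from meninges-free mouse forebrain at postnatal day 6, with 3 biological replicates labelled ctrl and 3 labelled Ep400 cko, all on a mixed 129SvJ and C57Bl/6J background, per the labels. Libraries were made from total RNA with a stranded mRNA kit, per the labels' protocols. The p-values of single genes measure the spread between these samples. Those of gene lists, Fisher tests and permutations take genes as the units and do not measure that spread. Reads were aligned to mm10 with STAR 2.5.1, counted with HTSeq and compared with DESeq2, tools named by the submitters' processing notes in no stated order. The strand setting of the counting is not given in the sources used here, so antisense and overlapping genes are uncertain, as are pseudogenes and gene families with near-identical copies.

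The deposited file is a table of the authors' own comparison with Ensembl release 85 identifiers, per the file headers, and it holds 0 columns of values per sample. The authors gave each gene a mean signal over all libraries, a normalised read count. Its header speaks of raw counts, but 0 of the means are multiples of 1/6 within 1e-06, so the values had been scaled. The authors' log2 fold change and its log2 standard error are moderated towards 0, which was read from the values: a gene with 132 reads in 1 ctrl library and 0 reads in the 5 others is listed at -0.14. Fold changes of low or variable genes are thus smaller than the ratio of the means. The authors' deposited score is the Wald statistic, the fold change over its standard error. The authors' deposited p-value and its Benjamini-Hochberg adjusted p-value follow from that score, and both could be recomputed from the table with a largest difference of 2.8e-15. The direction, cko over ctrl, is stated by the file's name and by no column.

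Of 48526 genes, 19785 had a mean of 0, 118 had a fold change but no p-value, 8522 had a p-value but no adjusted p-value because their mean lay under 6.1, and 20101 were tested. The main result is the authors' comparison at an adjusted p under 0.05. A count model of 3 against 3 libraries had been planned before the data were examined. It needs values per sample, so the plan's fallback, the authors' own comparison, took its place. Gene identifiers were matched to GENCODE M21 (GRCm38, the mm10 assembly) for 48144 genes, for coordinates, gene type, and the length and GC content of the longest transcript, and 382 did not match.

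The 32 gene lists were fixed before the data were examined. Each list with at least 5 tested members was tested against all other tested genes with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald statistic, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 31 lists. An estimated correlation needs values per sample, so correlations of 0.05 and 0.1 were used as alternatives. They were chosen after seeing the data, and 13 and 11 of the 15 calls held with them. With the gene values permuted 40 times, 3.3% of lists had a p under 0.05, and 72.5% of lists shifted by 1.5 were called. Permuting removes any correlation between genes, so these rates do not show how the test behaves for lists whose members vary together. Counts adjusted over the list alone apply Benjamini-Hochberg to the members' deposited p-values. The astrocyte list shares Slc1a3 with the radial glia list and Sox9 with the lineage factors, and the OPC list shares Ptprz1 with the radial glia list and Pdgfra and Cspg4 with the mural and fibroblast list. Many astrocyte markers are also expressed by OPCs or radial glia at lower levels.

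The genes named are, by a rule fixed before the data were examined, Ep400, the 12 genes with the largest fold change in each direction among those past an adjusted p of 0.05 with a mean of at least 50, up to 4 passing members per list with the smallest adjusted p, 14 fixed names of the lineage, p53 and the cell cycle, and the most abundant member of each list of other cell types. Symbols of predicted genes and of pseudogenes, and members of the sex-linked list, were left out of the largest changes. The rule's condition that the values of the groups do not overlap needs values per sample and could not be applied. Some genes that the rule names are not reported here. Opalin, Gata6, Matn4 and Srebf2 lie outside the rule and were chosen after their values were seen.

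Whole reads per library were worked out for genes with a mean of 6.1 to 40. A deposited mean is a sum over 6 libraries of whole reads times what 1 read is worth in that library, and the 6 worths were read from genes with 1 read in all. Each of the 4044 means was solved by exactly 1 set of reads within 2e-13, 0 of 300 shifted means had a solution, and 289 of 289 simulated means were recovered. The group of a library follows from the sign of the deposited fold change of genes read in that library alone. The libraries are called a, b and c within a group by falling scale factor, which is no replicate number. Tests on these reads used limma-trend on log2(normalised reads + 1). In data simulated for 4013 genes it called 48.5% of 200 genes changed 4-fold, and 3% of its calls were unchanged genes. The simulation gave all libraries the same spread, whereas the real ctrl libraries were more uneven, so these rates need not hold for the real reads. Principal components used the 1000 most variable of these genes. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

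Alternatives were a stricter threshold, no filter on low genes, a mean of at least 80, protein-coding genes alone, the Wald statistic after removing trends with transcript length and GC content, other forms of the list test, and on the recovered reads other pseudocounts and leaving out each library.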

Results

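Poly(A) RNA was sequenced from oligodendrocyte precursor cells (OPCs), the dividing glial cells that give rise to myelin-forming oligodendrocytes, taken from mouse forebrain at postnatal day 6. The animals carried Cre recombinase under the promoter of Cnp, an oligodendroglial gene, and a Rosa26 reporter that turns on YFP after recombination. Cells were sorted by YFP and by Hoechst, a DNA stain. There were 2 groups with 3 samples each, called ctrl and Ep400 cko, the conditional knockout of Ep400. Ep400 is the ATPase of the EP400/TIP60 complex, which places histone variants such as H2A.Z into chromatin. The comparison asks which transcripts differ when OPCs lack Ep400. The values come from the authors' deposited table of this comparison, which lists 48526 genes by mean normalised read count, log2 fold change and test. The means in that table sum to 80407433 normalised reads per library, and the 6 libraries' scale factors, worked out from the lowest genes, ran from 0.967 to 1.122. Totals per named sample were not analysed here.

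Ep400 itself did not differ in the authors' deposited table. Its mean normalised read count was 12048, with a log2 fold change of 0.01 ± 0.17 (SE; 95% interval -0.33 to 0.35; adjusted p = 0.97). The gene lies on chromosome 5 from 110664373 to 110770717 on the minus strand (mm10). A count over a whole gene does not resolve the floxed exons, so this value checks neither the deletion nor the direction of the comparison, which rests on the file's name.

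In the Ep400 cko samples, 16 of 20 astrocyte markers rose and 14 of 20 markers of pericytes, smooth muscle and fibroblasts fell. Genes of committed and mature oligodendrocytes lay lower as groups, although few of them passed the test singly. The cholesterol synthesis list was higher and the ribosomal protein list lower, although most members did not pass singly. At an adjusted p under 0.05, 2462 of the 20101 tested genes differed, of which 1535 were higher and 927 lower in Ep400 cko. The fold changes in the authors' deposited table are moderated towards 0, and 619 genes rose and 300 fell by at least 1 on this log2 scale.

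**Figure D1:**
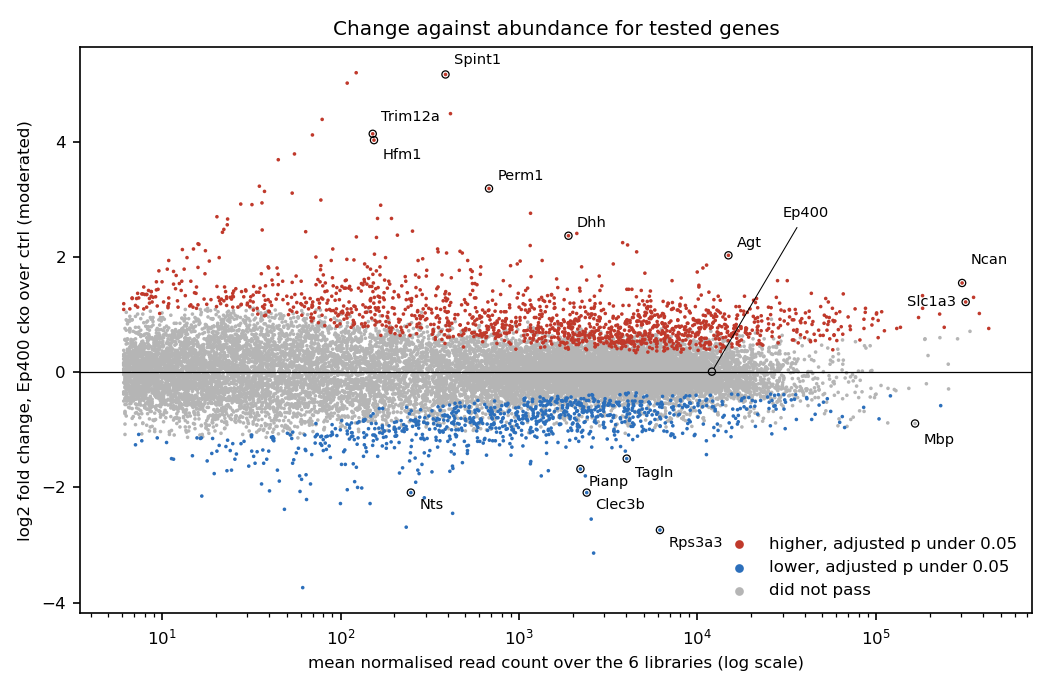
Log2 fold change of Ep400 cko over ctrl (vertical axis, moderated by the authors) against the mean normalised read count over the 6 libraries (horizontal log axis), with 1 point per tested gene. Red points are the 1535 genes higher and blue points the 927 genes lower at an adjusted p under 0.05, grey points did not pass, and circles mark named genes such as Spint1 at 5.17 and Ep400 at 0.01.

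The oligodendrocyte lineage was examined from precursor to myelin. Of 22 OPC markers, 4 rose, 2 fell and 16 did not pass, or 5 higher and 2 lower when adjusted over the list alone. The list had a median log2 fold change of 0.00 and an adjusted p of 0.40. Ptprz1, a receptor phosphatase of precursors and radial glia, rose by 1.30 ± 0.31 (SE, log2) and the proteoglycan gene Cspg5 by 0.93 ± 0.27 in the authors' deposited table. C1ql1 fell by 1.03 ± 0.29 and the matrix gene Matn4 by 1.01 ± 0.34 in the authors' deposited table. With trends in transcript length and GC content removed, Cspg5 and C1ql1 no longer passed (adjusted p = 0.056 and 0.052). Pdgfra, the PDGF receptor of OPCs, stood at -0.03 ± 0.29 in the authors' deposited table (adjusted p = 0.97) and Cspg4, which encodes NG2, at -0.33 ± 0.23 (adjusted p = 0.37).

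Among 26 transcription factors of the oligodendroglial lineage, Id2 rose and 25 did not pass, as was also the case when adjusted over the list alone. The list median was -0.22 and its adjusted p 0.41. The lineage factors Olig1 and Olig2 stood at -0.30 ± 0.22 and -0.41 ± 0.24 in the authors' deposited table (adjusted p = 0.41 and 0.29). Sox10, which drives oligodendrocyte differentiation, stood at -0.88 ± 0.41 and Myrf, which turns on myelin genes, at -0.78 ± 0.42 in the authors' deposited table (adjusted p = 0.15 and 0.22).

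All 18 tested markers of committed and premyelinating oligodendrocytes had negative fold changes with a median of -0.68, and the list was lower with an adjusted p of 0.00045. None of them passed singly, over all genes or adjusted over the list alone. Gpr17, a receptor of the committed stage, stood at -0.88 ± 0.41 in the authors' deposited table (adjusted p = 0.15). The list of myelin and mature oligodendrocyte genes was lower too, with a median of -0.78 and an adjusted p of 5.2e-05. Of its 26 tested members 3 fell, 1 rose and 22 did not pass, with the same numbers when adjusted over the list alone. The authors' deposited table gave -1.22 ± 0.42 for the myelin glycoprotein gene Mog, -0.96 ± 0.23 for Cryab and -0.50 ± 0.18 for the transferrin gene Trf, whereas Aspa rose by 1.35 ± 0.33. With length and GC trends removed, Mog and Trf no longer passed (adjusted p = 0.063 and 0.074), nor did Trf with no filter on low genes (adjusted p = 0.062). The myelin genes Mbp and Cnp stood at -0.89 ± 0.41 and -0.67 ± 0.42 in the authors' deposited table (adjusted p = 0.14 and 0.32). The deposited standard errors of the myelin list were high, with a median of 0.41 against 0.20 in expression-matched lists. Such a moderated error need not rise with unevenness between libraries, as a gene with 132 reads in 1 ctrl library alone had 0.178. In the reads recovered per library, Opalin, a myelin membrane gene, had 149 reads in 1 ctrl library, 15 and 30 in the other ctrl libraries, and 4, 16 and 21 in the Ep400 cko libraries.

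**Figure D2:**
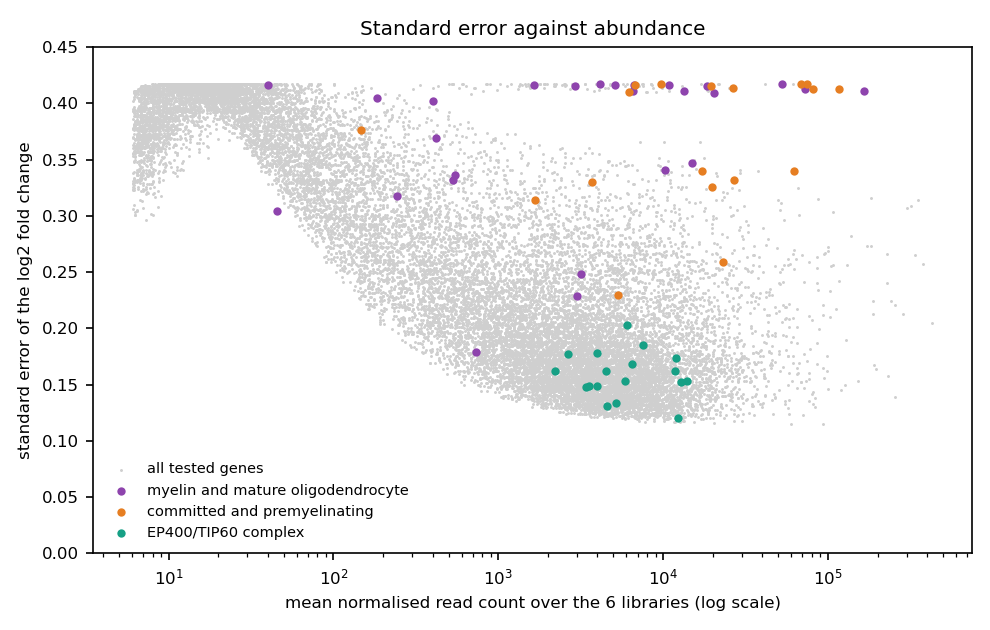
Standard error of the log2 fold change (vertical axis, log2 units) against the mean normalised read count over the 6 libraries (horizontal log axis), for all tested genes in grey and 3 gene lists in colour. Myelin genes have a median standard error of 0.41, and most stand near the table's largest value of 0.417, while Ep400 complex genes lie near 0.157.

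Markers of other cell types moved in different directions, so each list is given with its own count and test. Of 20 astrocyte markers 16 rose, none fell and 4 did not pass, also when adjusted over the list alone, with a list median of 1.04 and an adjusted p of 4.4e-12. In the authors' deposited table Agt, which encodes angiotensinogen, rose by 2.03 ± 0.25, the glutamate transporter gene Slc1a2 by 1.33 ± 0.32, the water channel gene Aqp4 by 1.14 ± 0.27 and Fgfr3 by 1.11 ± 0.26. Of 14 radial glia and neural stem cell markers 7 rose and 7 did not pass, the same when adjusted over the list alone, with a median of 0.58 and a list adjusted p of 0.00057. The authors' deposited table gave 1.22 ± 0.31 for the glutamate transporter gene Slc1a3, 1.04 ± 0.32 for the matrix gene Tnc and 0.77 ± 0.22 for Hopx, of which Tnc no longer passed with length and GC trends removed (adjusted p = 0.059). The mean in the authors' deposited table was 318172 normalised reads for Slc1a3, which both the astrocyte and the radial glia list hold, beside 19690.5 for Pdgfra and 24362.6 for Olig2.

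Of 24 neuron markers 5 rose and 19 did not pass, the same when adjusted over the list alone, with a median of 0.21. Slc17a7, a vesicular glutamate transporter gene, rose by 1.96 ± 0.37 and Reln, which encodes reelin, by 0.89 ± 0.20 in the authors' deposited table. Grin2b, which also rose, no longer passed with length and GC trends removed (adjusted p = 0.21). The most abundant neuron marker, Map2, stood at 0.21 ± 0.12 in the authors' deposited table (adjusted p = 0.29). The neuron list had an adjusted p of 0.0078, and adjusted p = 0.06 and 0.16 at inter-gene correlations of 0.05 and 0.1. Of 6 red blood cell markers 4 rose and 2 did not pass, the same when adjusted over the list alone, with a median of 0.97 and a list adjusted p of 0.0032. The haemoglobin genes Hbb-bt and Hba-a1 rose by 1.29 ± 0.30 and 0.98 ± 0.35 in the authors' deposited table, and Hba-a1 no longer passed with no filter on low genes (adjusted p = 0.063).

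Of 20 markers of pericytes, smooth muscle and vascular fibroblasts 14 fell, none rose and 6 did not pass, or 16 lower when adjusted over the list alone. The list median was -0.92 and its adjusted p 9.4e-12. In the authors' deposited table the smooth muscle genes Tagln, Acta2 and Myh11 fell by 1.5 ± 0.27, 1.43 ± 0.27 and 1.31 ± 0.30, and Des, which encodes desmin, by 1.12 ± 0.25. Rgs5, the most abundant of these markers, stood at -0.68 ± 0.25 in the authors' deposited table and did not pass (adjusted p = 0.058), although it did with length and GC trends removed (adjusted p = 0.020) and among genes with a mean of at least 80 (adjusted p = 0.049). Of 20 microglia and macrophage markers 5 fell and 15 did not pass, or 12 lower when adjusted over the list alone, with a median of -0.44 and an adjusted p of 5.2e-06. The complement gene C1qa fell by 0.68 ± 0.19, P2ry12 by 0.59 ± 0.18 and Cx3cr1 by 0.61 ± 0.19 in the authors' deposited table. Csf1r, the growth factor receptor of microglia, had a mean of 129373 normalised reads in the authors' deposited table, and its value of -0.32 ± 0.19 did not pass (adjusted p = 0.28). Of 18 endothelial markers 2 fell and 16 did not pass, the same when adjusted over the list alone, with a median of -0.25 and a list adjusted p of 0.095. The 2 that fell, Esam and Eng, no longer passed with length and GC trends removed (adjusted p = 0.073 and 0.057). The endothelial list passed downward with no filter (adjusted p = 0.036) and in the rank form (adjusted p = 0.039), over a range of 0.036 to 0.38 in all alternatives. Of 16 ependymal and choroid plexus markers 6 fell and 10 did not pass, or 7 lower and 2 higher when adjusted over the list alone, with a median of -0.48 and a list adjusted p of 0.12. The 6 that fell were cilia genes and their regulators, among them Foxj1, a factor of multiciliated cells, by 0.99 ± 0.27 and Rsph1 by 1.08 ± 0.30 in the authors' deposited table. The most abundant endothelial and choroid plexus markers, Slc2a1 and Ttr, stood at 0.42 ± 0.20 and 0.92 ± 0.41 in the authors' deposited table (adjusted p = 0.16 and 0.13).

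**Figure D3:**
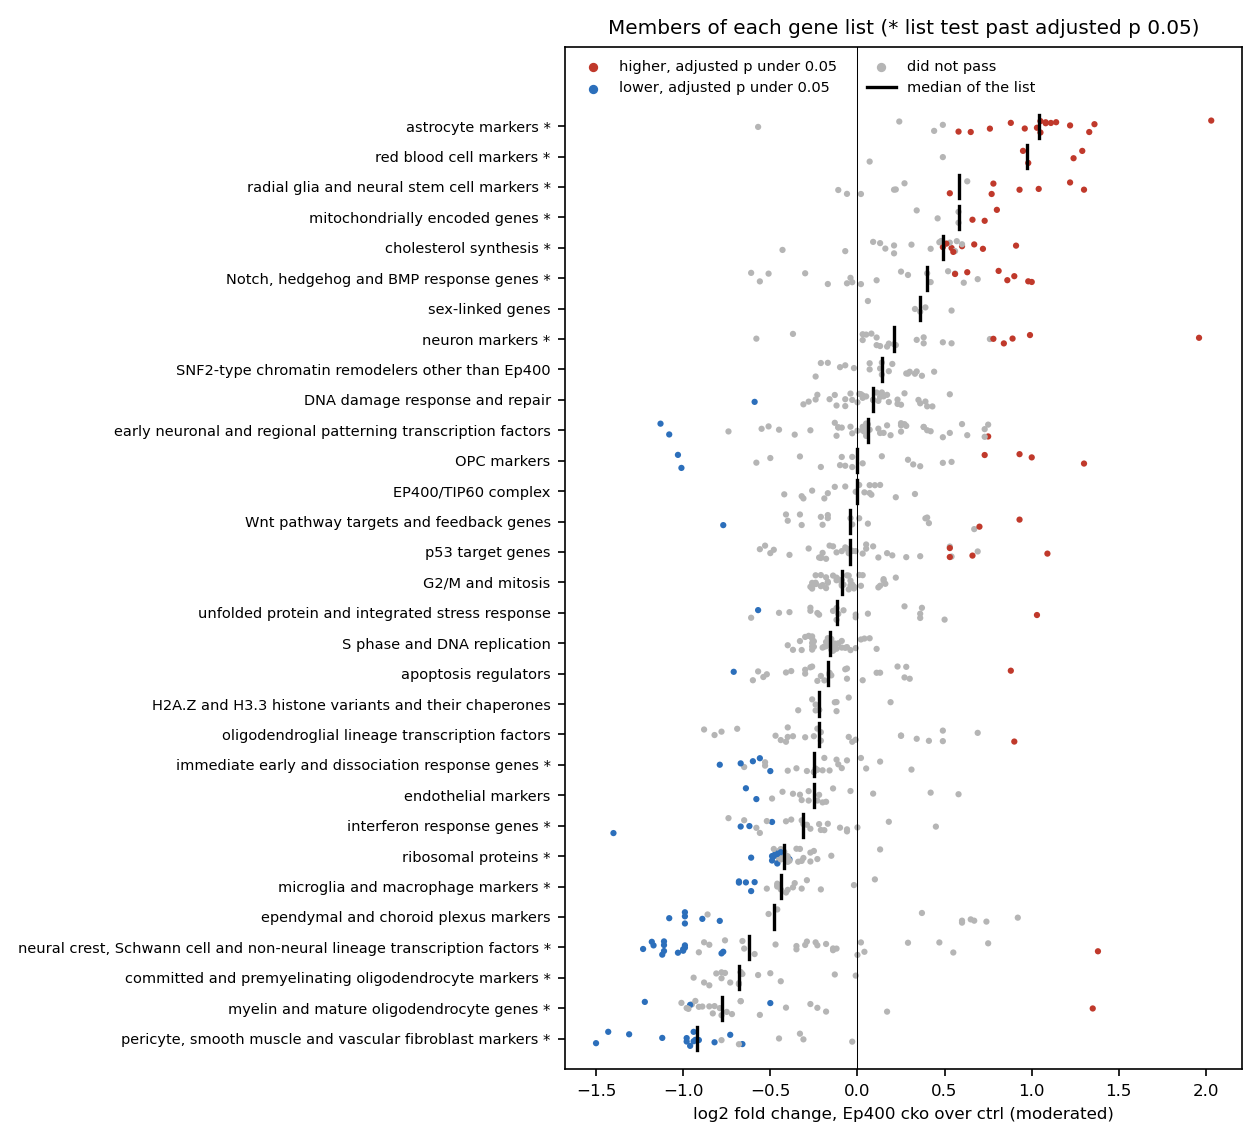
Log2 fold change of Ep400 cko over ctrl for the tested members of each of the 31 gene lists tested, with 1 point per gene and a black bar at the list median (horizontal axis, log2 units, moderated by the authors). Red and blue points are genes higher or lower at an adjusted p under 0.05, grey points did not pass, and an asterisk marks the 15 lists past an adjusted p of 0.05, from astrocyte markers at a median of 1.04 to mural and fibroblast markers at -0.92.

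Genes of the deleted protein's own complex and of related chromatin factors were then compared. None of the 18 tested members of the EP400/TIP60 complex passed, singly or adjusted over the list alone, with a median of 0.00 and a list adjusted p of 0.53. The same held for 20 other SNF2-type remodelers, with a median of 0.14 and a list adjusted p of 0.12, and for 11 genes of H2A.Z and H3.3 histone variants and their chaperones, with a median of -0.22 and a list adjusted p of 0.22.

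Proliferation and damage genes showed few single changes. None of the 40 S phase and 40 mitosis genes passed, also adjusted over the list alone, with medians of -0.16 and -0.09 and list adjusted p of 0.072 and 0.35. The S phase list passed downward with no filter on low genes (adjusted p = 0.021) and in the rank form of the test (adjusted p = 0.016), over a range of 0.016 to 0.39 in all alternatives. Mki67, a marker of dividing cells, stood at 0.13 ± 0.23 in the authors' deposited table (adjusted p = 0.76). Of 38 p53 target genes 4 rose and 34 did not pass, the same when adjusted over the list alone. They were Ddit4l at 1.09 ± 0.20, Zmat3 at 0.53 ± 0.14, Ddb2 at 0.66 ± 0.20 and Trp53inp1 at 0.53 ± 0.19 in the authors' deposited table. Trp53inp1 no longer passed with length and GC trends removed (adjusted p = 0.22) or with no filter on low genes (adjusted p = 0.060). The p53 list had a median of -0.04 while its test pointed up, with an adjusted p of 0.72. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at -0.39 ± 0.17 in the authors' deposited table, the p53 ligase gene Mdm2 at -0.07 ± 0.17 and Trp53 itself at -0.30 ± 0.21 (adjusted p = 0.10, 0.84 and 0.38). Of 37 DNA damage response genes Parp1 fell by 0.59 ± 0.21 in the authors' deposited table and 36 did not pass, with an adjusted p of 0.057 for Parp1 under no filter on low genes. None of the 37 passed when adjusted over the list alone, with a median of 0.09 and a list adjusted p of 0.41. Among 28 apoptosis regulators the survival gene Bcl2 rose by 0.88 ± 0.25 and the death receptor adaptor gene Tradd fell by 0.71 ± 0.22 in the authors' deposited table, and 26 did not pass. Neither passed with length and GC trends removed (adjusted p = 0.066 for Bcl2 and 0.062 for Tradd). Adjusted over the list alone, 1 rose and 1 fell, with a median of -0.17 and a list adjusted p of 0.075. The apoptosis list passed downward with no filter (adjusted p = 0.025) and in the rank form (adjusted p = 0.035), over a range of 0.025 to 0.38 in all alternatives.

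Metabolic and translation genes moved as groups. Of 23 cholesterol synthesis genes 8 rose, none fell and 15 did not pass, or 14 higher and 1 lower when adjusted over the list alone. The list median was 0.49 and its adjusted p 1.7e-05, and the list moved in the direction of the astrocyte markers, at a median of 1.04. In the authors' deposited table Fdps, which makes farnesyl diphosphate, rose by 0.60 ± 0.17 and Srebf2, its transcriptional regulator, by 0.51 ± 0.18. Of 40 ribosomal protein genes 10 fell and 30 did not pass, or 33 lower when adjusted over the list alone, with a median of -0.42 and a list adjusted p of 6.7e-12. Rpl35 fell by 0.61 ± 0.18 and Rps6 by 0.49 ± 0.15 in the authors' deposited table, and neither passed singly with length and GC trends removed (adjusted p = 0.052 and 0.074). Of 7 tested mitochondrially encoded genes 3 rose and 4 did not pass, or 6 higher when adjusted over the list alone, with a median of 0.58 and a list adjusted p of 0.00088. They included mt-Nd5 at 0.80 ± 0.24 and mt-Nd4 at 0.66 ± 0.20 in the authors' deposited table.

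Among 25 Notch, hedgehog and BMP response genes 7 rose and 18 did not pass, or 10 higher and 1 lower when adjusted over the list alone, with a median of 0.40. The hedgehog genes Ptch1, Gli3 and Gli1 rose by 0.98 ± 0.23, 1.00 ± 0.27 and 0.81 ± 0.23 in the authors' deposited table, and Id2 by 0.90 ± 0.26. The list had an adjusted p of 0.0078, and adjusted p = 0.06 and 0.16 at inter-gene correlations of 0.05 and 0.1. Gli1, Gli3 and Ptch1 rose, as did the astrocyte markers, at a list median of 1.04. Of 19 Wnt targets and feedback genes 2 rose, 1 fell and 16 did not pass, the same when adjusted over the list alone, with a median of -0.04 and a list adjusted p of 0.75. The feedback gene Znrf3 rose by 0.93 ± 0.25 and Nkd2 fell by 0.77 ± 0.22 in the authors' deposited table.

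The list of non-neural lineage factors was lower, as were the mural and fibroblast markers at a list median of -0.92. Of 40 tested factors of neural crest, Schwann cells and non-neural lineages 14 fell, 1 rose and 25 did not pass, or 16 lower and 2 higher when adjusted over the list alone. The list median was -0.62 and its adjusted p 7.2e-06. Foxd1, Foxc1 and Tbx3 fell by 1.11 ± 0.24, 1.03 ± 0.23 and 1.00 ± 0.23 in the authors' deposited table, whereas Msx2 rose by 1.38 ± 0.31. Gata6 had 44, 50 and 50 reads in the ctrl libraries and 13, 21 and 14 in the Ep400 cko libraries. Of 47 early neuronal and regional patterning factors Otx1 rose, Nkx6-1 and Lmx1b fell and 44 did not pass, or 1 lower and none higher when adjusted over the list alone, with a median of 0.06 and a list adjusted p of 0.70. Otx1 no longer passed with length and GC trends removed (adjusted p = 0.079) or with no filter on low genes (adjusted p = 0.070). Of the Hox genes 3 were tested and none passed, also adjusted over the list alone, which left too few for a list test.

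Stress and immune response lists lay lower or did not pass. Of 26 immediate early and dissociation response genes 5 fell and 21 did not pass, or 6 lower when adjusted over the list alone, with a median of -0.25 and a list adjusted p of 0.00088. Klf2 fell by 0.67 ± 0.15 and Atf3 by 0.79 ± 0.26 in the authors' deposited table, and Atf3 no longer passed with length and GC trends removed (adjusted p = 0.059). That list had adjusted p = 0.017 and 0.074 at inter-gene correlations of 0.05 and 0.1. Of 25 interferon response genes 4 fell and 21 did not pass, the same when adjusted over the list alone, with a median of -0.31 and a list adjusted p of 0.00045, and with adjusted p = 0.010 and 0.053 at inter-gene correlations of 0.05 and 0.1. Ifi44 fell by 1.40 ± 0.27 in the authors' deposited table. The interferon list was lower, as were the microglia markers, at a list median of -0.44. Of 22 unfolded protein and integrated stress response genes Slc7a11 rose, Sdf2l1 fell and 20 did not pass, with the same numbers when adjusted over the list alone, a median of -0.12 and a list adjusted p of 0.70. With length and GC trends removed neither gene passed (adjusted p = 0.10 for Slc7a11 and 0.14 for Sdf2l1), and with no filter Sdf2l1 did not (adjusted p = 0.058). None of 5 tested sex-linked genes passed, also adjusted over the list alone, with a median of 0.36 and a list adjusted p of 0.24.

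The largest changes of single genes lay outside these lists. Spint1, which encodes a membrane inhibitor of serine proteases, rose by 5.17 ± 0.32 in the authors' deposited table (adjusted p = 1.1e-54; chromosome 2 from 119237362 to 119249527, mm10). The authors' deposited table listed Hfm1, a meiotic helicase gene, at 4.03 ± 0.33, the muscle regulator gene Perm1 at 3.19 ± 0.33, Vill at 2.90 ± 0.33, Nsun7 at 2.76 ± 0.30 and Ppfia4 at 2.41 ± 0.23. Dhh, which encodes desert hedgehog, rose by 2.37 ± 0.42, Fam227b by 2.35 ± 0.41, Metap1d by 2.25 ± 0.21 and the potassium channel gene Kcnk1 by 2.20 ± 0.21 in the authors' deposited table. Trim12a at 4.14 ± 0.40 and Cldn34c1 at 4.12 ± 0.39 in the authors' deposited table are uncertain, since both belong to families of near-identical genes. Among the lower genes, the authors' deposited table gave -2.09 ± 0.27 for Clec3b, -2.09 ± 0.30 for the neurotensin gene Nts, -2.07 ± 0.38 for Ch25h, -2.04 ± 0.37 for the smooth muscle gene Cnn1 and -2.01 ± 0.35 for Lyzl4. Col6a6 at -1.86 ± 0.40, Ptx4 at -1.78 ± 0.39, Pianp at -1.68 ± 0.16, Dlk2 at -1.67 ± 0.39 and Adgrg5 at -1.66 ± 0.27 followed in the authors' deposited table. Cnn1 fell, as did the mural markers, at a list median of -0.92. Rps3a3 at -2.74 ± 0.33 and Bcl2a1d at -1.65 ± 0.34 in the authors' deposited table share sequence with close copies and are uncertain as well.

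Gene types differed in direction. Among 774 tested lincRNA genes 86 were higher and 13 lower, and among 645 loci of the class to be experimentally tested (TEC) 87 were higher and 1 lower. Processed pseudogenes went the other way, with 18 of 775 higher and 58 lower. Protein-coding genes made up 16004 of the tested genes, of which 1213 were higher and 813 lower.

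For genes with a mean from 6.1 to 40, the whole reads of each library could be worked out from the deposited means, although the libraries cannot be tied to replicate numbers. Across these genes the 3 Ep400 cko libraries resembled each other more than the ctrl libraries did, with Spearman correlations of 0.51 to 0.69 against 0.22 to 0.35. The median tested gene had a mean of 1189.1, so correlations over such low genes do not describe the libraries as a whole. Ctrl library a correlated more closely with the Ep400 cko libraries, at 0.36 to 0.48, than with ctrl libraries b and c, at 0.349 and 0.344, and those correlated with the Ep400 cko libraries at 0.15 to 0.23. Across the 4044 genes, ctrl library b had 914 and ctrl library c 650 genes with 0 reads, against 136 in ctrl library a and 44 to 79 in the Ep400 cko libraries. On the first principal component, with 49.6% of the variance, ctrl library a scored 3.0, ctrl libraries b and c -68.8 and -36.3, and the Ep400 cko libraries 26.3 to 38.3. On these reads limma-trend called 9 genes higher and none lower at an adjusted p under 0.05, with 568 at an unadjusted p under 0.05, where the authors' deposited table calls 141 higher and 42 lower. Without ctrl library c it called 31 genes, without ctrl library b 23, and without ctrl library a 5. When any single Ep400 cko library was left out, limma-trend called 0 genes, with 313 to 446 at an unadjusted p under 0.05.

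**Figure D4:**
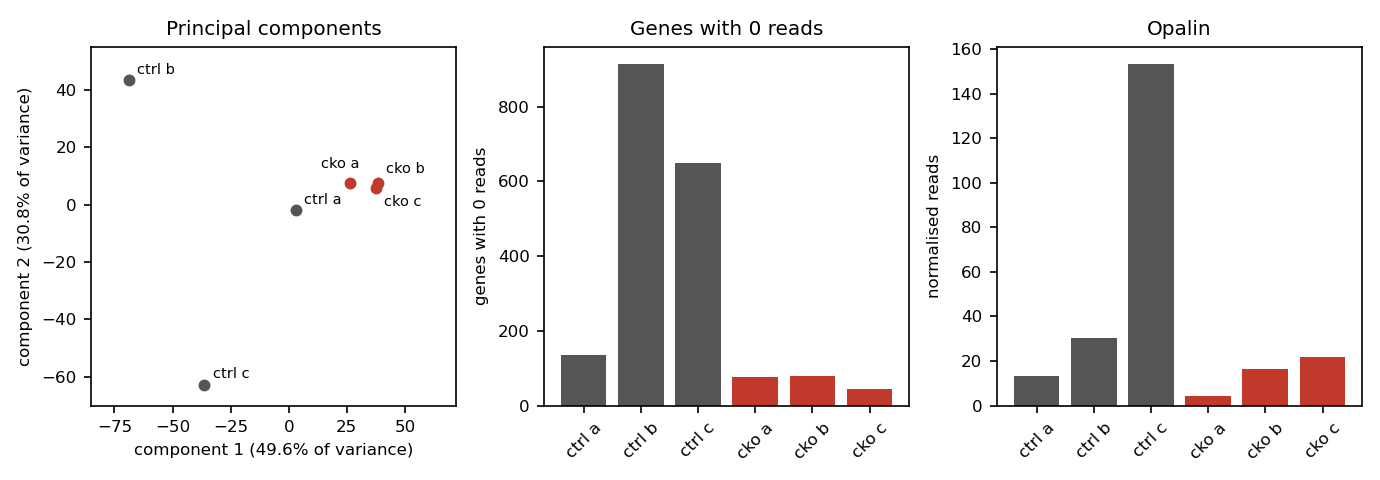
Reads recovered per library for 4044 genes of low expression, with ctrl libraries in grey and Ep400 cko libraries in red. The left panel plots the first 2 principal components (49.6% and 30.8% of variance), the middle panel the number of genes with 0 reads (914 in ctrl library b), and the right panel the normalised reads of Opalin, highest in ctrl library c.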

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

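All tests in this part were chosen after the data were seen. For the test of transcript length and GC content, the ratio over the genes called higher and the splits of the libraries, the deciding bound was set before that test's own value was seen.

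The authors' deposited table gives a fold change but no p-value for 118 genes, which the tests above leave out. They stand out by direction, as 112 are lower and 6 higher in Ep400 cko. The 6 most abundant in the authors' deposited table are Neu4 at -0.85, Pllp at -0.95, Bmp4 at -0.88, Gal3st1 at -1.01, Tspan2 at -1.29 and Tmeff2 at -0.78 on the log2 scale. Of 50 genes in the committed and myelin lists 6 had no p-value, against 42 of 20099 other genes with a mean as high (Fisher exact test, two-sided p = 1.9e-09). Among the 31 such genes with recovered reads, 21 had their highest value in ctrl library c and 7 in ctrl library b. A high value in 1 ctrl library alone makes a fold change negative. The shared direction thus need not reflect the ctrl libraries as a group, and the reason for the missing p-values was not tested.

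The cell type lists moved apart, with astrocyte markers higher, and mural, fibroblast, microglia and oligodendrocyte genes lower. A lower share of oligodendroglial cells as the only change would raise the markers of every other type alike. The astrocyte median was instead 1.04 and the microglia median -0.44, a difference of 1.49 (permutation test over genes, two-sided p = 4e-05). Both medians were known before this test, and its p takes marker genes as the units. It therefore adds nothing to the medians and does not measure the spread between libraries. More astrocyte RNA in the Ep400 cko libraries remains open, as 80% of the astrocyte markers rose and the abundant Slc1a3 rose with them, although the YFP sort was meant to leave such cells out. An oligodendrocyte share that differs between libraries of 1 genotype also remains open. The standard errors of the myelin list lay at percentile 100 of matched lists. A moderated standard error need not rise with unevenness between libraries, so that percentile cannot decide. OPC, astrocyte, neuron, mural and cell cycle lists also reached percentile 100, so reaching it is not particular to myelin genes. Their median standard errors, from 0.245 for OPC to 0.339 for neuron markers, lay under the 0.41 of myelin and 0.393 of committed genes. Opalin was highest in ctrl library c, but it was picked after its values were seen. There, 124 of the genes with recovered reads were more than 3 times as high as in every other library. A change of gene activity within the sorted cells is the biological alternative, and it was not tested.

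The ribosomal protein list was lower, and more non-coding genes were called higher than lower, although most did not pass. A bias by transcript length or GC content as the whole cause of the ribosomal list's shift is argued against, because the list kept an adjusted p of 5.7e-09 after both trends were removed, although fold changes followed length and GC with Spearman correlations of 0.17 and -0.19 across 20015 genes. Thinner sampling of low transcripts in ctrl libraries b and c remains open for the non-coding genes. Of 1467 non-coding genes, 394 and 296 had 0 reads in these libraries, against 61 in ctrl library a. Both libraries also lay farther from the Ep400 cko libraries. Over all 4044 genes, however, ctrl library c had 71927 reads, close to the 71999 of ctrl library a, and ctrl library b had 62310. The Ep400 cko libraries had 65143, 74154 and 72323, so a lower read total does not account for the zeros of ctrl library c. The summed reads of 1467 non-coding genes in ctrl library a were 0.79 of the Ep400 cko mean (95% interval over genes 0.76 to 0.82). Ctrl libraries b and c stood at 0.74 and 0.90. Ctrl library a thus neither reached the Ep400 cko mean nor exceeded both others, as thinner sampling would predict, but this rests on 1 library. Over the 141 genes called higher, its median log2 ratio to the Ep400 cko mean was -2.57. That value lay past the bound set beforehand as counting against thinner sampling. The bound was not applied, because these genes were picked for low ctrl reads, so neither value decides. An effect of Ep400 loss was not tested.

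Large changes of single genes may come from inherited differences on the mixed 129SvJ and C57Bl/6J background. Large changes were those with an adjusted p under 0.05 and at least 1.5 on the log2 scale. Within 10 Mb of Ep400, 7 of 273 autosomal genes had one, against 201 of 19045 elsewhere. The odds ratio was 2.47 (95% interval 0.97 to 5.25; Fisher exact test, two-sided p = 0.029). The interval includes 1 although the p is under 0.05, and 7 genes are few. A segment carried along with the floxed allele thus remains open for a few of them, such as Hfm1. Elsewhere, 9 neighbouring pairs of large changes were found where permuted calls gave 1.8 in the mean (permutation p = 0.0003), among them Tyr and Grm5 on chromosome 7, and these made up 7 places when pairs sharing a gene counted once, against 1.8 (permutation p = 0.002). Such pairs do not single out inherited segments, since related genes such as Mcpt1 and Mcpt2 or parts of a single transcript would also pair, and at Gm5148 the neighbours changed in opposite directions. Most large changes lie in neither set, and an effect of Ep400 loss on them was not tested.

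Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes among the recovered reads as the real split, which is the real split itself, with 9 genes against at most 0 in the others. The splits are too few for a share under 0.05.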

How the results depend on the processing

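The lists' alternatives other than no filter, the mean of at least 80, the protein-coding and trend-removed settings, the gene calls on recovered reads and the component over all of them were chosen after seeing the data. At an adjusted p under 0.01, 1197 genes were called, 828 higher and 369 lower, and with a fold change tested against 1.5 there were 118, 86 higher and 32 lower, as stricter settings call fewer. The counts with no filter (2103), a mean of at least 80 (2370), protein-coding genes alone (2090) and trends removed (2089) stayed within 1.5 times the main count. Among the recovered reads, limma-trend called 0 genes with a pseudocount of 0.1 (468 at an unadjusted p under 0.05) and 79 with 10, and 0 to 31 when each library was left out. The first component took 57% of the variance with 500 genes and 41.4% with all. No list and no named gene turned its direction past the threshold. At correlations of 0.05 and 0.1, 2 and 4 of 31 list calls were lost, and with trends removed 1 was, the neuron markers (adjusted p = 0.051). With no filter and in the rank form 3 list calls each were gained, all lower: apoptosis (adjusted p = 0.025 and 0.035), S phase (0.021 and 0.016) and endothelial (0.036 and 0.039). Of 122 named genes 112 kept their side of the threshold with no filter and 96 with trends removed, which 25 lost. The cause of these losses was not tested. No paired analysis was possible because the table has no values per sample and the recovered libraries cannot be tied to replicate numbers. For the same reason other normalizations, a filter on depth-scaled counts, voom, a refit with DESeq2, a replicate block, leave-one-out over the whole table, an estimated list correlation, fry and components over the larger planned gene set were not run. The main result does not cover the lowest genes, as 8522 with a mean under 6.1 had a p-value but no adjusted p-value. These entered only the settings with no filter.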

Other observations

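The groups and tests in this part were chosen after the values were seen.

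Many of the most abundant transcripts of these sorted cells rose. Of the 50 tested genes with the highest mean, 22 rose, 3 fell and 25 did not pass. In the authors' deposited table Ncan, which encodes the proteoglycan neurocan, rose by 1.55 ± 0.31, the fatty acid desaturase gene Scd2 by 1.02 ± 0.26, and Apoe, a lipid carrier gene, by 0.76 ± 0.20. The GABA transporter gene Slc6a11 rose by 1.11 ± 0.27 and Mfge8 by 0.95 ± 0.27 in the authors' deposited table. The 3 that fell in the authors' deposited table were Actb at -0.58 ± 0.16, which encodes a cytoskeletal actin, Col4a1 at -0.81 ± 0.26, a basement membrane collagen gene, and Sparc at -0.41 ± 0.14. Several of the genes that rose are known from astrocytes, whose marker list had a median of 1.04.

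The most uneven transcripts between libraries lay in ctrl. Among the genes with recovered reads, 124 were more than 3 times as high in ctrl library c as in every other library, 45 in ctrl library b and 7 in ctrl library a, against 3, 6 and 3 in the Ep400 cko libraries. The tight junction gene Cldn14 had 160 reads in ctrl library c and 7 and 8 in the other ctrl libraries. Gh, the growth hormone gene, had 132 reads in ctrl library a and 0 in the 5 others.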
